A study of Rattus norvegicus with 4 samples.

How the data were processed

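Liver RNA of male rats was compared 3 h after common bile duct ligation (CBDL), an operation that blocks the outflow of bile, and 3 h after a sham operation in which the duct was exposed but left open. Per the labels' protocols, RNA of 3 rats per condition was mixed, poly(A) RNA was purified from the mix, and both conditions were labelled by reverse transcription with cyanine dyes and hybridised together to a glass slide of spotted cDNA. There were 4 such arrays. CBDL carried Cy5 on arrays 1 and 3 and Cy3 on arrays 2 and 4, so each dye orientation was represented by 2 arrays.

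The values deposited by the authors, read here as log2 ratios of both channels, cover 1936 probes on each array with no missing value; how they were made is not given in the sources used here beyond the labels' protocols. Spot intensities were not analysed here, and scanner software, background correction and normalization are not named by the labels, so the signal over background of a spot is not known and the number of arrays limits the precision. The base and the direction of the deposited log ratios are not stated by the labels. They were read as log2 of channel 2 (CBDL) over channel 1 (sham) on every array, a direction that is likely and not certain. Its basis is that channel 2 holds CBDL on all 4 arrays. Probes of the same gene resembled each other more in the mean of the 4 arrays than in the difference between the dye orientations, which bears on whether the ratios follow the dyes and not on their sign. The array medians as deposited were -0.33, 0.84, -0.20 and 0.83 for arrays 1 to 4, so the deposited values were not centred on the median.

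Probes were named through the platform annotation of 2007. Of the 1936 probes, 1432 carried 1 gene symbol (958 genes), 19 carried several and 485 carried none; the labels state 1800 genes on the array. Symbols were updated through gene identifiers with a table of the rat assembly GRCr8, in which 1429 identifiers matched and 3 did not, and the symbol of the annotation was kept otherwise. No genome coordinates are printed, because no build is named for the clones. Unnamed probes and probes with several symbols stayed in the fit and out of the counts of named genes.

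Each array was centred on its median and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a CBDL over sham effect and a dye term for each probe. This left 2 residual degrees of freedom per probe before moderation, and fewer in the fits that left out an array. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all 1936 probes, with a threshold of 0.05. The fit was repeated on the mean of the probes of each of the 958 genes, adjusted over those genes, and these means are the values given for members of gene lists. Errors are standard errors (SE) of the fit over 4 arrays, with a median of 0.059 and a range of 0.055 to 0.146 on the log2 scale over all probes.

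The p-values measure the spread between arrays. The labels describe 1 pool of RNA per condition and do not say that the arrays came from separate pools, so this spread may be technical only. Every test therefore compares these RNA pools and not the rats or the operations in general.

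A total of 30 gene lists was fixed before the data were examined, as were the grouping, the tests, the threshold, the rule for named genes and the other settings listed first below. The 24 lists with at least 5 measured genes were tested with limma's camera against all other genes (preset inter-gene correlation of 0.01, two-sided, Benjamini-Hochberg over the 24 lists), and with an estimated correlation (statmod 1.5.0) as an alternative. That alternative rests on the 2 residual degrees of freedom of the fit, on which an adjusted p under 0.05 is hardly within reach. Its lack of calls therefore decides nothing about a list. Per direction, the rule named the 12 genes with the largest change among probes past the threshold whose 4 centred log ratios had the same sign. It also named up to 4 members of each list past the threshold, or up to 2 members as values where none passed, and Cyp7a1, Abcb11, Slc10a1, Abcc2, Abcc3, Nr0b2, Alb, Gapdh and Actb. Abcb11, Abcc3, Alb and Gapdh had no probe with their symbol alone and were not analysed here. Members named besides these, to complete a count, were chosen after their values were seen.

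The fit was tested on simulated arrays with the spread of the real ones. It recovered 50 of 50 probes at each of 1.25-, 1.5-, 2- and 4-fold, with 14 false calls among 1736 unchanged probes, 6.54% of all calls. In the list test, the shifted list was called and 0 of 20 unshifted lists were. The simulated rises and falls were balanced and most probes unchanged, so the zero point could not err and was not tested. The simulated genes of the list test varied independently, so the effect of correlation between genes was not tested either.

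The design written beforehand took opposite signs between the dye orientations as a mark of ratios formed by dye. Over all probes the orientations did correlate negatively, so by that rule the ratios would be read by dye. The rule was set aside after the data were seen, because probes of the same gene resembled each other more in the mean than in the difference between orientations. A dye component was computed for each probe from the deposited values. It is 0.5 times the difference between the mean log ratio with CBDL in Cy5 and that with CBDL in Cy3. Other settings fixed beforehand were the values as deposited, scaling to equal median absolute deviation, quantile normalization, no dye term, robust moderation, other thresholds, averaging of probes, a turned sign, rank correlation and leaving out each array. Settings chosen after seeing the data were centring along the dye component (lowess span 0.3), centring on probes with a dye component above -0.2, leaving out the unnamed spots at repeated positions, leaving out probes with a dye component under -1, and reading the ratios as Cy5 over Cy3.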

Results

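The data were log ratios of 1936 probes on 4 cDNA arrays, each hybridised with liver RNA of rats 3 h after ligation of the common bile duct and liver RNA of sham-operated rats, pooled from 3 rats per condition. The comparison asks which liver transcripts differ at this early time after bile flow is blocked. Values are log2 ratios of CBDL over sham after median centring, with the standard error of the fit over 4 arrays. The log base and the sign are readings of the deposited values and not stated by the labels; with the opposite sign every direction below would turn. The arrays compare 1 described pool of RNA per condition, so the p-values measure the spread between arrays and not between rats.

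Nr0b2, a nuclear receptor that represses bile acid synthesis, had the largest rise among named genes, 4.83-fold at its probe with the larger change (2.27 ± 0.06), and its other probe gave 2.22. Egr1, an immediate early transcription factor, rose 3.33-fold (1.74 ± 0.08), and Alpl, the alkaline phosphatase of liver and bone, 3.22-fold (1.69 ± 0.07; 1.32 at its other probe). The autophagy adaptor Sqstm1 rose by 1.23 ± 0.07, liver glycogen synthase Gys2 by 1.20 ± 0.06, the interferon-induced GTPase Mx2 by 1.18 ± 0.07 and the NF-kappaB inhibitor Nfkbia by 1.12 ± 0.06. Cathepsin S (Ctss) rose by 1.10 ± 0.06, Cyp2c22 by 1.05 ± 0.06, and all 3 probes of Cyp2c22 were at 0.81 or above. For the remaining 3 genes named on this side, probes of the same gene differed in sign. Rxrg, a retinoid X receptor, gave 1.34 at its higher probe and -0.04 at the other. The amino acid transporter Slc38a2 gave values from -0.24 to 1.29 over 5 probes, and the chemokine Ccl6 from -0.12 to 1.00 over 4.

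Among named genes that fell, the splicing factor Prpf6 changed most (-1.37 ± 0.06), followed by the transcriptional regulator Tsc22d1 (-1.26 ± 0.06) and the fatty acid desaturase Fads2 (-1.13 ± 0.06, and -1.05 at its other probe). The vasopressin receptor Avpr1a fell by 1.06 ± 0.09, apolipoprotein A-I (Apoa1) by 1.02 ± 0.06 and carbonic anhydrase Car3 by 1.05 ± 0.06, with -0.83 at the other Car3 probe. Cyp2f4 was at -0.94 and -0.79, the acyl-CoA synthetase Acsl1 at -0.94 and -0.86, and lactate dehydrogenase Ldha at -0.91 and -0.74 at both of their probes. Car2 (-1.12) and the hydroxyacid oxidase Hao2 (-1.10) fell at a single probe each, with 0.05 and 0.15 at the other. Cdk1, a cell cycle kinase, ranged from -1.02 to -0.02 over 5 probes. Adjusted p for the 12 named genes of each direction, at the probe named, lay between 7.37e-11 and 4.74e-07 (limma). The same sign of the centred ratio on all 4 arrays was a condition of the rule. Of all probes with 1 symbol that passed at 1.5-fold or more, 37 of 40 higher and 41 of 48 lower had it.

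Of the 1432 probes with 1 symbol, 557 passed an adjusted p of 0.05, 161 higher and 396 lower after CBDL (649 at an unadjusted p under 0.05). At 1.5-fold or more, 40 probes of 28 genes were higher and 48 probes of 39 genes were lower, and these 88 passed with the same sign in every other centring tried (3 fixed beforehand, 2 chosen after seeing the data), in both reduced probe sets, and without each array in turn. Their size, at least 0.585 on the log2 scale with SE of at most 0.086, exceeds the shifts of the median between these centrings (-0.03 to 0.28), so such changes of the zero could hardly end these calls. With the ratios read as Cy5 over Cy3, the reading that the rule written beforehand would give, 34 of the 88 passed with the same sign and 51 had the opposite sign. Without array 3 the 557 became 367 and the 396 lower became 251. Without a dye term limma called 0 of the 88, with 86 named probes at an unadjusted p under 0.05. The balance of smaller changes depended on the zero point. Lower probes made 71.1% of the 557, 8.61% of 999 in the values as deposited, 7.53% of 1009 after quantile normalization and 43.1% of 362 after centring along the dye component. Of the 557 calls, 247 passed with the same sign as deposited and 0 with the opposite sign; after quantile normalization these numbers were 237 and 32. Lower probes made 29.8% of 568 after centring on probes with a dye component above -0.2. Without the spots at repeated positions they made 60.5% of 527, and without probes of a dye component under -1 they made 56.9% of 552. The median of all probes moved from -0.06 to 0.22 in the deposited values, a shift of 0.28. The centring thus leaned low: the subtracted array medians had a mean of 0.28, above the median of 0.22. Grouped by dye component, the probes had medians of 0.13 to 0.27 as deposited, so every group's median lay under 0 after centring. The 396 lower against 161 higher owe a part to this. The labels name no reference for 0. Unnamed spots at 3 positions repeated in every block averaged 0.00 ± 0.03 (SD, 48 spots) as deposited, and whether they or the array median mark no change is open, so the falls listed below that did not pass as lower as deposited rest on that choice.

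**Figure D1:**
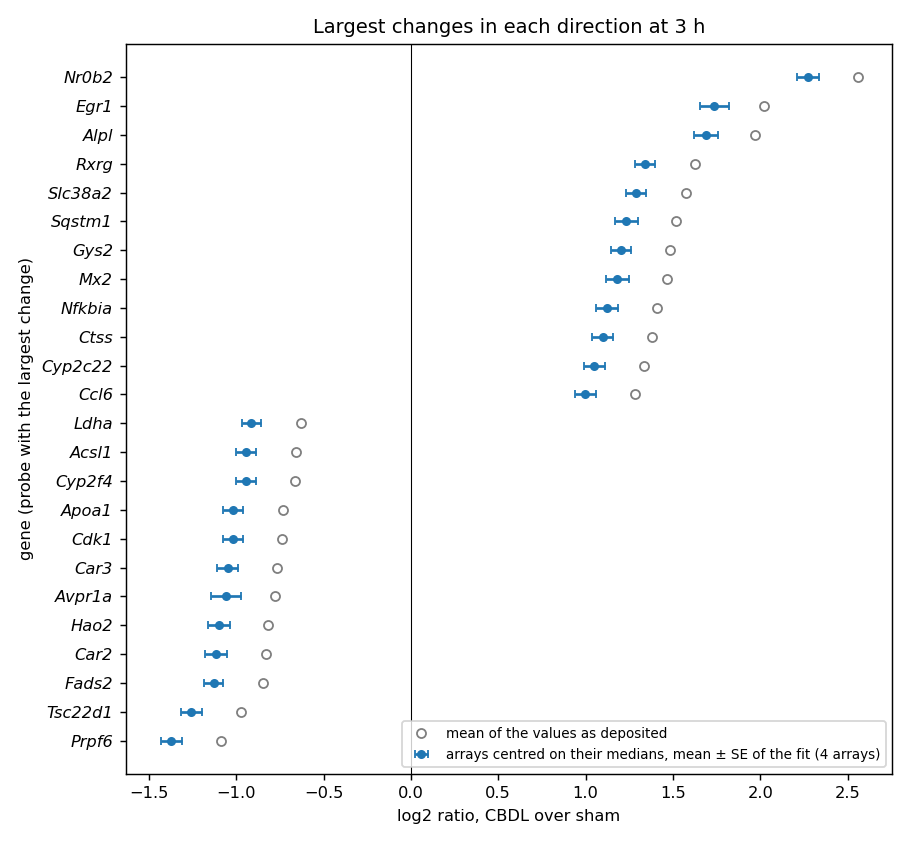
Log2 ratio of CBDL over sham (horizontal axis) for the 12 genes with the largest change in each direction, at the probe with the larger change; filled points with bars are the mean ± SE of the fit over 4 median-centred arrays and open circles the mean of the deposited values. Nr0b2 stands highest at 2.27 and Prpf6 lowest at -1.37, and both kinds of point lie on the same side of 0 for every gene drawn.

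Nr0b2 was high on each array. Its centred log ratio at the named probe was 2.71 and 2.71 on arrays 1 and 3, with CBDL in Cy5, and 1.68 and 1.98 on arrays 2 and 4, with CBDL in Cy3. Prpf6 was at -0.73 and -0.96 on the former and -1.98 and -1.81 on the latter. These gaps come from the centring, which subtracted medians of -0.33 and -0.20 on the former and 0.84 and 0.83 on the latter. In the deposited values the dye component was -0.11 for Nr0b2 and -0.03 for Prpf6, with means of 2.56 and -1.09. Over all 1936 probes, arrays of the same dye orientation correlated with Pearson's r of 0.946 (arrays 1 and 3) and 0.949 (arrays 2 and 4). Arrays of opposite orientation correlated negatively, from -0.486 to -0.366. These are correlations across probes, which are not independent replicates. The negative values came with 458 probes (23.7%) that had a dye component under -1, of which 272 carried 1 gene symbol. None of the 458 had a log2 ratio above 0.28 in size.

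**Figure D2:**
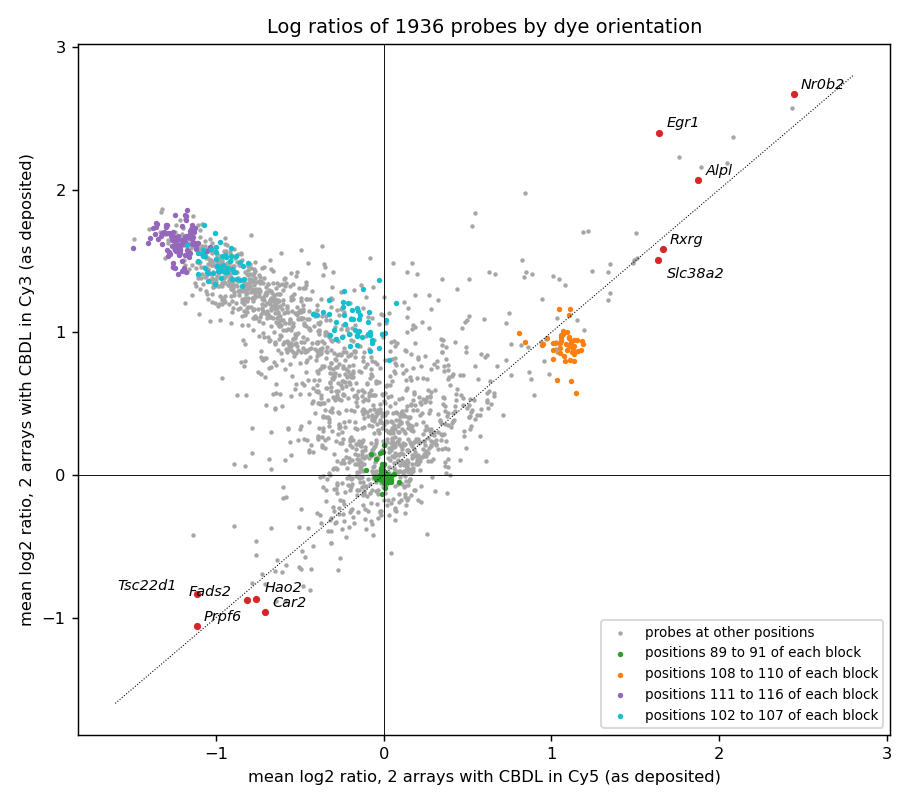
Mean deposited log2 ratio of each of 1936 probes on the arrays with CBDL in Cy5 (horizontal axis) against the mean on those with CBDL in Cy3 (vertical axis); red points are the 5 largest changes per direction, coloured points the unnamed spots at positions repeated in every block, and the dotted line marks equal values. Nr0b2 and Prpf6 lie near the line and Egr1 above it (dye component -0.378), while a band of probes runs to the upper left, where the dye component is under -1.

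Gene lists fixed before the data were examined are described by the mean of each gene's probes. Of 86 list members and fixed genes that passed and are named by the rule, 44 kept their direction and their call in 7 other centrings or probe sets (3 fixed beforehand, 4 chosen after seeing the data). The other 42 were all on the lower side and lost the call, or turned, in at least 1 of the 7. Cdk1 and Stat5b did so after quantile normalization only and passed as deposited (adjusted p = 0.0495 and 0.0362), while the others of the 42 did not pass as lower as deposited. Among the genes named below these are Slc10a1, Fosl2, C3, Serpina3n, Gc, Ttr, Tf, Vtn, Fgg, Gstm2, Echs1, Cpt1a, Acadl, Scd2, Pklr, Cyp51, Mvk, Pgk1, Stat5b, Igfals, Igfbp4, Igfbp1, Fah, Bckdk, Agxt, Nr3c1, Fth1, Gpx1, Pdia4, Ddit3, Cdk1, Casp6, Rps28, Rpl4, Rpl3, Rpl35a, Atp5pb, Cox8a, Mmp14, Timp2, Lck and Kdr. Of list members named besides the rule, Cyp8b1 lost its call as deposited, Slco1a4 after quantile normalization and Apoa4 in both. Apart from scaling to equal median absolute deviation (a shift of -0.03), these settings moved the median of all probes upward, by 0.04 to 0.28, so they put falls to the test more than rises. The setting without a dye term, also fixed beforehand, is not among the 7. In it 1 gene passed in the bile acid list and 1 in the immediate early list. In the negative acute phase, fatty acid oxidation and inflammatory lists 0 passed. For Cyp8b1, Slco1a4, Cpt1a, Dusp6 and Cdk1 the mean joins a probe past 1.5-fold with another within 0.2 of 0.

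Leaving out an array also ended calls. Such a fit has fewer residual degrees of freedom, and its spread comes only from the orientation that keeps both arrays. A lost call can therefore reflect that weaker estimate of the spread and not the value on the array left out. Of the 86, 3 lost the call without array 1, 23 without array 2, 4 without array 3 and 32 without array 4, 35 without at least 1 of them, and 0 turned. On the higher side these were Odc1, Il1a, Ccn2, Fabp4, Serping1, Xbp1, Pawr, Bcl2a1, S100a10 and Tmsb10. On the lower side they were Slc10a1, Fgg, Serpina3n, C3, Tf, Ttr, Gc, Pdia4, Mvk, Acadl, Echs1, Pklr, Scd2, Igfbp1, Agxt, Fah, Rpl35a, Rpl3, Cox8a, Timp2, Mmp14, Ddit3, Casp6, Igfbp4 and Nr3c1. Fos, Aldoa and Npm1, named besides the rule, lost the call without array 4, and Dusp6 without array 2 or 4.

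Genes of bile acid synthesis and transport moved in both directions, and 3 of 8 measured genes rose and 4 fell. Nr0b2 rose by 2.25 ± 0.06 (adjusted p = 5.69e-07), the canalicular export pump Abcc2 by 0.49 ± 0.04 (0.00012) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by 0.45 ± 0.05 (0.000525). Nr1h4, the bile acid receptor FXR, fell by 0.60 ± 0.06. The sterol hydroxylase Cyp8b1 was lower relative to the array median (-0.41 ± 0.05), with -0.69 and -0.13 at its 2 probes, and did not pass as deposited (-0.13, adjusted p = 0.0626). The uptake transporter Slco1a4 (-0.42 ± 0.05) gave -0.81 and -0.04 at its 2 probes and -0.14 as deposited (adjusted p = 0.0430). The bile acid uptake transporter Slc10a1 fell relative to the array median (-0.20 ± 0.05, adjusted p = 0.0177), stood at 0.08 in the values as deposited and did not pass without array 2, 3 or 4. The list's median was -0.11 and its mean 0.19, and camera gave an upward direction with an adjusted p of 0.618. As deposited, 4 genes were higher and 2 lower.

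Among immediate early and stress transcription factors and among inflammatory genes, more rose than fell relative to the array median. Of 11 measured immediate early genes 5 rose, namely Egr1 (1.74 ± 0.09), Nfkbia (1.12 ± 0.06), the growth regulator Myc (0.83 ± 0.05), Fos (0.37 ± 0.06) and the MAP kinase phosphatase Dusp6 (0.23 ± 0.05), while Fosl2 fell relative to the array median (-0.37 ± 0.05). Of 16 inflammatory genes 6 rose, among them the NF-kappaB subunits Nfkb2 (0.39 ± 0.05) and Nfkb1 (0.32 ± 0.04) and the cytokine Il1a (0.28 ± 0.05). Tnf fell by 0.81 ± 0.05 in this list. Camera gave an adjusted p of 0.0364 for the immediate early list and 0.0471 for the inflammatory list, both upward, and an adjusted p of 0.856 for each with an estimated correlation. As deposited, 10 of 11 and 15 of 16 genes were higher, and the lists' adjusted p rose to 0.122 and 0.219. Without array 4, 3 immediate early and 2 inflammatory genes were higher and both lists had an adjusted p of 0.0862. The inflammatory list had 0.0792 without array 1, 0.0602 without array 2 (3 genes higher) and 0.0833 without array 3. Scaling to equal median absolute deviation gave 0.0506 for both lists.

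All 5 measured negative acute phase proteins, plasma proteins known to decline in inflammation, fell relative to the array median. Apoa1 changed most (-1.02 ± 0.05), followed by the vitamin D-binding protein Gc (-0.39 ± 0.06), transthyretin Ttr (-0.37 ± 0.06), transferrin Tf (-0.33 ± 0.06) and Apoa4 (-0.30 ± 0.04). Camera gave an adjusted p of 0.0364 (downward), and an adjusted p of 0.856 with an estimated correlation; in the values as deposited, Apoa1 alone of the 5 was lower, with the list's adjusted p at 0.00063. Without array 4, 2 of the 5 were lower and the list's adjusted p was 0.0862; it was 0.0506 after scaling to equal median absolute deviation. Of 14 acute phase genes 4 rose, including the transcription factor Cebpd (0.83 ± 0.06) and the plasma protein Orm1 (0.66 ± 0.07). A further 5 fell, including complement C3 (-0.37 ± 0.06) and the protease inhibitor Serpina3n (-0.27 ± 0.05), and in the values as deposited 9 were higher, 0 were lower and Serpina3n was at 0.0098. Of 5 coagulation and complement genes, the C1 inhibitor Serping1 rose (0.33 ± 0.07) and C3, vitronectin Vtn (-0.35 ± 0.05) and fibrinogen Fgg (-0.23 ± 0.06) fell; as deposited 2 were higher and 0 lower, with Fgg at 0.054. Camera gave an adjusted p of 0.449 for the acute phase list and 0.905 for coagulation and complement; the median of the latter was -0.23. In the acute phase list 2 genes were higher without array 1, 2 or 4, and 3 were lower without array 2 and 0 without array 4. In coagulation and complement 0 were higher without array 2 or 4, and 1 was lower without array 4.

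Of 19 genes for cytochrome P450 enzymes and their reductase, 12 fell and 4 rose relative to the array median; after centring along the dye component 5 were lower and 6 higher. Cyp2f4 (-0.87 ± 0.05), Cyp4f1 (-0.68 ± 0.05) and Cyp4f4 (-0.61 ± 0.05) fell, and Cyp2c22 rose (0.96 ± 0.05). Of the 4 that rose, the reductase Por and Cyp2c12 had probes of both signs (-0.27 to 0.69 and -0.07 to 0.56). Of 9 phase II genes 5 fell, among them the glutathione transferases Mgst1 (-0.91 ± 0.05), Gsta2 (-0.72 ± 0.05), Gstm5 (-0.66 ± 0.07) and Gstm2 (-0.37 ± 0.05), and the epoxide hydrolase Ephx2 rose (0.28 ± 0.05); adjusted over the list alone, 6 fell and 1 rose. Camera gave an adjusted p of 0.595 for the P450 list and 0.344 for phase II. Without centring, 3 P450 genes were lower and 8 higher, 3 phase II genes were lower and 3 higher, and the phase II list had an adjusted p of 0.0351. Without array 2 or without array 4, 7 P450 genes were lower, and 2 were higher without array 4.

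All 6 measured genes of fatty acid oxidation and ketogenesis fell relative to the array median, with Acsl1 (-0.90 ± 0.05), the enoyl-CoA hydratase Echs1 (-0.36 ± 0.10), the carnitine transferase Cpt1a (-0.35 ± 0.05) and the dehydrogenase Acadl (-0.25 ± 0.05) changing most. In lipogenesis Fads2 fell (-1.09 ± 0.05) and fatty acid synthase Fasn rose (0.84 ± 0.05); Scd2 (-0.25 ± 0.06) and the pyruvate kinase Pklr (-0.24 ± 0.05) fell too, so that 3 of 7 fell and 1 rose. In cholesterol synthesis and uptake 3 of 5 fell, namely the reductase Dhcr7 (-0.79 ± 0.05), Cyp51 (-0.38 ± 0.05) and mevalonate kinase Mvk (-0.30 ± 0.06). Camera gave an adjusted p of 0.0471 (downward) for fatty acid oxidation, with an adjusted p of 0.856 with an estimated correlation, and 0.946 for lipogenesis and 0.424 for cholesterol. Without centring, 1 gene of each of these lists was lower, and 0, 4 and 2 were higher in the same order, with Acadl at 0.038, Scd2 at 0.031 and Pklr at 0.039. Leaving out an array moved these counts: of the 6 fatty acid oxidation genes 3 were lower without array 2 and 2 without array 4, and 1 lipogenesis gene was lower without array 2 or 4. The adjusted p for fatty acid oxidation was 0.0602 without array 2, 0.0673 without array 3, 0.0862 without array 4 and 0.0594 after scaling to equal median absolute deviation.

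In glucose metabolism Gys2 rose (1.17 ± 0.05), as did the aldolase Aldoa (0.25 ± 0.05), while 9 of 17 genes fell, including Ldha (-0.83 ± 0.05), Ldhb (-0.59 ± 0.05) and the glycolytic kinase Pgk1 (-0.32 ± 0.05). Of 13 genes of the growth hormone, insulin and IGF axis 7 fell and 0 rose, with Igf1 (-0.64 ± 0.05), the signal transducer Stat5b (-0.45 ± 0.06), the IGF carrier Igfals (-0.33 ± 0.05) and Igfbp4 (-0.32 ± 0.09) changing most. In amino acid and urea metabolism ornithine decarboxylase Odc1 rose (0.24 ± 0.06), and 3 of 7 fell: the tyrosine-degrading enzyme Fah (-0.37 ± 0.08), the kinase Bckdk (-0.37 ± 0.05) and the aminotransferase Agxt (-0.28 ± 0.05). In the glucocorticoid and fasting list Cebpd rose and 3 of 8 fell: Cpt1a, the binding protein Igfbp1 (-0.28 ± 0.06) and the glucocorticoid receptor Nr3c1 (-0.19 ± 0.05). Adjusted over the list alone, 10 glucose genes and 8 genes of the growth hormone list fell. Camera gave adjusted p of 0.595, 0.116, 0.656 and 0.735 for these lists in the order given; the glucocorticoid list had a median of -0.07 against a mean of 0.01. In the values as deposited 2, 2, 0 and 0 genes were lower and 7, 5, 3 and 5 higher, with Agxt at 0.0071, Igfbp1 at 0.0063 and Nr3c1 at 0.098. Without array 2, 4 glucose genes, 3 of the growth hormone list and 1 of the glucocorticoid list were lower. Without array 4, 1 glucose gene was higher, and 1 gene was lower in the amino acid list and 1 in the glucocorticoid list. Odc1 did not pass without array 1, 2 or 4, and 2 glucocorticoid genes were higher without array 3.

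Stress lists held few changes of size apart from Sqstm1 (1.23 ± 0.06), a member of both the oxidative stress and the endoplasmic reticulum lists. Of 17 oxidative stress genes 6 fell and Sqstm1 alone rose. Superoxide dismutase Sod1 (-0.54 ± 0.05), ferritin Fth1 (-0.39 ± 0.06) and glutathione peroxidase Gpx1 (-0.36 ± 0.05) fell. Of 10 endoplasmic reticulum stress genes the transcription factor Xbp1 rose besides Sqstm1 (0.22 ± 0.05), while the chaperone Pdia4 (-0.34 ± 0.05) and Ddit3 (-0.14 ± 0.05) fell relative to the array median. Of 9 heat shock genes and chaperones P4hb (-0.45 ± 0.05) and Pdia4 fell and 0 rose. Camera gave adjusted p of 0.816, 0.595 and 0.816 for these lists; the endoplasmic reticulum list had a median of -0.07 against a mean of 0.07 and an upward test. The values as deposited had 11, 8 and 7 genes higher and 1, 0 and 1 lower, and Ddit3 was at 0.14. Without array 3, 2 oxidative stress genes and 1 heat shock gene were higher. In the endoplasmic reticulum list 1 was higher without array 2 or 4, and 1 was lower without array 2 and 0 without array 4; 1 heat shock gene was lower without array 4.

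Among cell cycle genes the cyclin Ccnd1 rose (0.66 ± 0.07) and Cdk1 fell (-0.42 ± 0.05), with the other 10 of 12 not passing. In the apoptosis list Pawr (0.26 ± 0.05) and Bcl2a1 (0.24 ± 0.05) rose and Casp6 (-0.21 ± 0.05) fell, of 9 genes. The cell cycle genes Ccne1, Ccnb1, Top2a and Rb1 and the apoptosis genes Apaf1, Birc2 and Bcl2l1 had dye components under -1. Over all probes between -1.2 and -1 the deposited means had a median of 0.24 and an SD of 0.076. Of these probes 13 of 196 passed. Neither the lack of calls nor the calls as deposited therefore tell much about those genes. Ccnd3, Cdkn3, Pcna, Cdc25b and Plk1 lay between -1 and -0.6, where the SD was 0.16 and 76 of 370 probes passed. Of 12 genes for ribosomal proteins and translation factors the nucleolar protein Npm1 rose (0.22 ± 0.05) and 5 fell, including Rps28 (-0.37 ± 0.06), Rpl4 (-0.35 ± 0.05), Rpl3 (-0.28 ± 0.05) and Rpl35a (-0.24 ± 0.05); adjusted over the list alone, 6 fell. Of 3 mitochondrial respiratory chain genes Atp5pb (-0.29 ± 0.05) and Cox8a (-0.21 ± 0.05) fell, too few genes for the list test. The 2 probes of Cox8a differed in sign, at -0.42 and 0.0075. In the cytoskeleton list vimentin Vim (0.43 ± 0.06), S100a10 (0.26 ± 0.05) and Tmsb10 (0.19 ± 0.05) rose of 8 genes, and beta-actin (Actb) was at 0.18 ± 0.07 with an adjusted p of 0.0869. The 3 probes of Tmsb10 differed in sign, from -0.03 to 0.34. Camera gave adjusted p of 0.595 for cell cycle, 0.595 for apoptosis, 0.706 for translation and 0.122 for the cytoskeleton, and the median and mean of cell cycle were -0.02 and 0.01 and those of apoptosis -0.04 and 0.01. In the values as deposited 11, 8, 7 and 7 genes of these lists were higher and 1, 0, 0 and 0 lower, with Casp6 at 0.073, Rpl3 at 0.0045, Rpl35a at 0.045 and Cox8a at 0.076; of the 3 respiratory chain genes 1 was higher and 0 lower. Without array 1, 2 cell cycle genes were higher. In the apoptosis list 1 was higher without array 2 and 0 without array 4, and 0 were lower without array 2 or 4. Without array 2, 3 translation genes were lower, and Npm1 did not pass without array 4. Without array 2 or without array 4, 1 respiratory chain gene was lower and 1 cytoskeleton gene higher.

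Markers of other cell types were sparse on this array. Of 15 extracellular matrix and stellate cell genes the growth factor Ccn2 (0.58 ± 0.09) and Vim rose, Mmp14 (-0.31 ± 0.09) and Timp2 (-0.22 ± 0.07) fell, and the collagen Col1a1 was at -0.07. Of 3 macrophage and Kupffer cell markers Ctss rose (1.10 ± 0.05), while Ctsb was at -0.02 and Fcgr2b at -0.01. Of 3 neutrophil and lymphocyte markers the T cell kinase Lck fell (-0.43 ± 0.05). None of 4 cholangiocyte markers passed, with Ggt1 at -0.06 and Spp1 at 0.05. The receptor Kdr fell (-0.35 ± 0.05) among 5 endothelial markers, and the single erythrocyte marker, Epor, was at -0.03. Of 4 markers of muscle, fat, gut and pancreas the fatty acid-binding protein Fabp4 rose (0.24 ± 0.05). Camera gave adjusted p of 0.358 for the matrix list, with a median of -0.01 against a mean of 0.04, and 0.905 for the endothelial list; the other marker lists were too small for it. In the values as deposited 13 matrix and 4 endothelial genes were higher and 0 lower, with Timp2 at 0.060, Ggt1 at 0.23 and Epor at 0.26. All 4 cholangiocyte markers, all 3 macrophage markers, all 4 markers of muscle, fat, gut and pancreas, 2 of 3 neutrophil and lymphocyte markers and Epor were then higher. After centring on probes with a dye component above -0.2, 2 cholangiocyte markers were. Spp1, Cd24 and Ggt1 had dye components of -1.14, -1.18 and -1.26. Over all probes under -1.2 the deposited means had a median of 0.23 and an SD of 0.062. Between -1.2 and -1 these were 0.24 and 0.076. Neither the lack of calls nor the calls as deposited therefore tell much about these markers. Without array 2 or without array 4, 1 matrix gene was higher and Fabp4 did not pass, and 1 matrix gene was lower without array 2 or 3 and 0 without array 4.

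**Figure D3:**
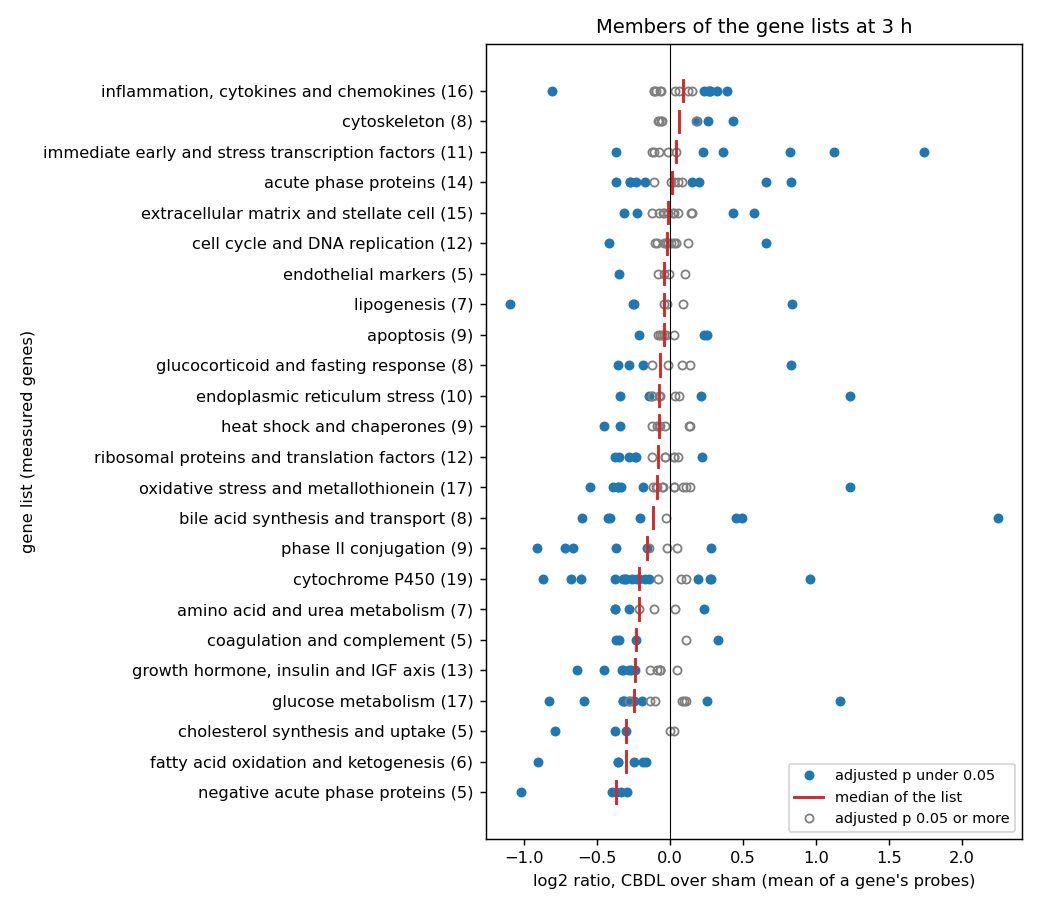
Log2 ratio of CBDL over sham (horizontal axis, mean of the probes of a gene, median-centred arrays) of each measured gene in the 24 lists with at least 5 measured genes; filled points passed an adjusted p of 0.05, open points did not, and red bars are list medians. The medians run from -0.37 for negative acute phase proteins to 0.09 for inflammatory genes, and the point farthest to the right is Nr0b2 at 2.25.

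Outside the lists named above with a different count, adjusting over the list alone gave the same number of genes in each direction as adjusting over all 958 genes, except in coagulation and complement, where Clu (0.11 ± 0.05) was added as a second gene on the higher side. With an estimated correlation camera called 0 of the 24 lists, and 0 had an unadjusted p under 0.05. On 2 residual degrees of freedom that version could hardly call a list, so its lack of calls decides nothing. The preset correlation called 4, and 6 had an unadjusted p under 0.05.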

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

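The search for arrays that stand apart was a rule fixed in advance; the choice to list unnamed probes of at least 2-fold was made after the data were seen.

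Ccnd1 stood apart on array 3, with a centred log2 ratio of 0.99 against 0.50 to 0.58 on the others (a gap of 0.829004 of the range, barely past the tabulated 95% critical value of Dixon's test for 4 samples). Timp2 stood apart on array 4 at -0.53, against -0.14 to -0.10 (0.920 of the range). Nr3c1 stood apart on array 2 at -0.34, against -0.15 to -0.13 (0.909 of the range). These were 3 of 114 genes and probes examined with that test, and chance alone singles out about 1 in 20 sets of 4 like samples. That share need not apply here, since the arrays fall into 2 dye orientations of 2 arrays each and a dye difference hides a single large gap. The test used centred ratios, and centring shifts the orientations against each other. As deposited the orientations differed for Ccnd1, Timp2 and Nr3c1 (dye components -0.43, -0.44 and -0.50), so that these stood apart depends on the centring.

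Probes without a gene symbol also held changes of over 2-fold. Unnamed probes 1220, 1510, 1880 and 1671 were higher after CBDL by 1.94, 1.74, 1.71 and 1.21 on the log2 scale, with SE of 0.059, 0.067, 0.060 and 0.057 over 4 arrays. Probe 585, whose annotation gives both Slfn4 and Cdk107, was higher by 1.83 ± 0.06. Outside the spots at repeated positions, 84 of 197 unnamed probes passed an adjusted p of 0.05 (limma), 28 higher and 56 lower, and 10 of 19 probes with several symbols passed.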

How the results depend on the processing

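Centring along the dye component, centring on probes with a dye component above -0.2, both reduced probe sets and the reading as Cy5 over Cy3 were chosen after the results were seen. Counts are of named probes, given as total, higher, lower, higher by 1.5-fold or more and lower by 1.5-fold or more; in the reported setting they were 557, 161, 396, 40 and 48, with 4 lists called by camera. As deposited, which adds 0.28 to the mean ratio of every probe, they were 999, 913, 86, 84 and 19, and after quantile normalization 1009, 933, 76, 88 and 12. Centring along the dye component gave 362, 206, 156, 53 and 27, and centring on probes with a dye component above -0.2 gave 568, 399, 169, 60 and 27. Averaging the probes of each symbol first tested 958 genes in place of 1432 probes and gave 354, 102, 252, 22 and 23. Adding the 1.5-fold threshold left 88, and turning the sign of every array gave 396 higher and 161 lower by construction. Reading the ratios as Cy5 over Cy3 gave 1210, 712, 498, 151 and 161, with 51 of the 88 at the opposite sign. Without a dye term limma called 0 probes in total, 0 higher, 0 lower, 0 higher by 1.5-fold and 0 lower by 1.5-fold. At an unadjusted p under 0.05 there were 86. Differences between the dye orientations then count as spread. They include an offset from the centring, since the subtracted medians were -0.33 and -0.20 with CBDL in Cy5 and 0.84 and 0.83 in Cy3. Probes with a dye component near 0 as deposited, such as that of Sqstm1 (-0.0052), carry this offset too. Leaving out each array in turn gave totals of 367 to 484, 116 to 142 higher, 251 to 353 lower, 38 to 43 higher by 1.5-fold and 42 to 50 lower by 1.5-fold; the lowest total and the 251 came without array 3. Thresholds of 0.01 and 0.1 gave 419 and 640 probes, robust moderation 566 and scaling to equal median absolute deviation 601. In place of 4 lists, camera called 3 as deposited (2 of the 4, and phase II), 2 after quantile normalization, 1 after centring along the dye component, 2 after centring on probes with a dye component above -0.2, 2 without the spots at repeated positions and 0 to 3 with an array left out. Camera called 0 lists without array 4 (5 at an unadjusted p under 0.05) and 0 after scaling to equal median absolute deviation (6 unadjusted, lowest adjusted p 0.0506), and the cause was not tested. It also called 0 with an estimated correlation (0 unadjusted), where 2 residual degrees of freedom leave a call hardly possible. Treating every probe as a member gave 6. Mean Spearman correlations were -0.582 between opposite and 0.941 between like dye orientations, against Pearson means of -0.420 and 0.947. No paired analysis was possible because the 4 arrays form a single group, in which each array already holds both conditions. Filters on missing values were not run, since no value was missing. The signal over background of the spots is not given in the sources used here.

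A change of sign is not a call as higher, and Ggt1 and Epor had not passed as lower (adjusted p = 0.413 and 0.672, limma). Among the genes named by the rule, those whose sign turned from negative to positive were all within 0.36 of the median. As deposited these were Serpina3n (0.0098), Acadl (0.038), Scd2 (0.031), Pklr (0.039), Agxt (0.0071), Rpl3 (0.0045), Rpl35a (0.045), Cox8a (0.076), Timp2 (0.060), Ggt1 (0.23), Epor (0.26), Fgg (0.054), Ddit3 (0.14), Casp6 (0.073), Igfbp1 (0.0063), Nr3c1 (0.098) and Slc10a1 (0.081). After quantile normalization they were Serpina3n (0.036), Gpx1 (0.0075), Acadl (0.044), Scd2 (0.051), Pklr (0.072), Agxt (0.051), Rpl35a (0.071), Atp5pb (0.043), Cox8a (0.13), Timp2 (0.065), Ggt1 (0.19), Epor (0.25), Fgg (0.089), Ddit3 (0.20), Casp6 (0.083), Igfbp1 (0.024), Nr3c1 (0.095) and Slc10a1 (0.13). Along the dye component Cox8a (0.0048) and Ddit3 (0.059) turned, and with centring on probes with a dye component above -0.2 Ddit3 (0.013) did. Genes that changed sign without passing in either setting compared, such as Epor and Ggt1 with the latter centring, are not listed. Of genes named besides the rule, those that turned as deposited were Fabp7 (0.0048), Ccl5 (0.18), Col1a1 (0.21), Ctsb (0.26), Fcgr2b (0.27), RT1-N3 (0.27), Slc22a3 (0.27), Slc22a5 (0.18) and Slco1c1 (0.25); all 9 turned after quantile normalization too.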

Other observations

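The gene families and the tests on the dye orientations were chosen after the results were seen; the test on probes of the same gene was written down before its result, and its comparison with pairs of different genes was added afterwards.

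Carbonic anhydrases, which interconvert carbon dioxide and bicarbonate, were lower in 3 of 4 measured genes. Car3 fell by 0.94 ± 0.05, Car1 by 0.57 ± 0.05 and Car2 by 0.53 ± 0.05, each also lower as deposited (-0.66, -0.28 and -0.25). Car4 was at 0.05 ± 0.05 and at 0.33 as deposited. The means join probes that disagreed for Car4 (-0.30 and 0.40) and for Car2 (-1.12 and 0.05). All 4 measured members of the Cyp4f family of fatty acid hydroxylases fell relative to the array median, with Cyp4f6 at -0.34 ± 0.05 and Cyp4f17 at -0.41 ± 0.11 besides Cyp4f1 and Cyp4f4; as deposited Cyp4f6 (adjusted p = 0.378) and Cyp4f17 (0.326) did not pass, and Cyp4f17 did not pass without array 4. Among fatty acid-binding proteins Fabp5 rose by 0.84 ± 0.09, Fabp3 by 0.28 ± 0.05 and Fabp4 by 0.24 ± 0.05, and Fabp7 fell (-0.28 ± 0.05) but was at 0.0048 as deposited.

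Of 8 measured uptake transporters of the Slco and Slc22a families, 4 passed as lower relative to the array median, and as deposited 4 passed as lower and 4 as higher. Slc22a8 fell by 0.75 ± 0.06, Slc22a18 by 0.58 ± 0.05, Slco2b1 by 0.52 ± 0.05 and Slco1a4 by 0.42 ± 0.05, and all 4 stayed lower as deposited (-0.47, -0.30, -0.23 and -0.14). The other 4 measured members, Slc22a3, Slc22a5, Slc22a6 and Slco1c1, did not pass relative to the median and passed as higher as deposited (0.27, 0.18, 0.40 and 0.25, adjusted p of 0.0202 or less). Dye components were -1.34 for Slc22a3, -1.15 for Slco1c1 and -1.02 for Slc22a6. Over all probes the deposited median was 0.23 at a dye component under -1.2 and 0.24 between -1.2 and -1. Passing as higher as deposited therefore says little about Slc22a3 and Slco1c1. Slco1a4 did not pass after quantile normalization. The membrane protein Ms4a6a rose by 0.92 ± 0.05. Of 2 measured RT1 genes, class I antigens, RT1-CE1 rose by 0.66 ± 0.05 and RT1-N3 was at -0.01 ± 0.05. Of 2 chemokines of the Ccl family Ccl6 rose by 0.57 ± 0.05 over its 4 probes. Ccl5 was at -0.11 ± 0.05, the mean of probes at -0.36 and 0.15. RT1-N3 and Ccl5 were at 0.27 and 0.18 as deposited.

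The negative correlation between opposite dye orientations raises the question whether the deposited ratios follow the dyes. If they did, the dye component would be the CBDL effect and probes of the same gene should resemble each other in it. Over 340 genes with several probes (814 probes), the intraclass correlation was 0.362 for the dye component and 0.615 for the mean of the 4 arrays, a difference of -0.253 (95% bootstrap interval -0.390 to -0.084), which argues against ratios formed by dye. It says nothing on the sign, since the value for the mean is the same with every sign turned. A dye offset of dim spots may account for the correlation instead, although the brightness of the spots was not measured. The SD of the mean ratio was 0.062 over 262 probes with a dye component under -1.2. It was 0.448 over 703 above -0.2, a ratio of 0.139. Many of the 262 repeat unnamed spots, such as those at positions 111 to 116 (96 spots, dye component -1.43, SD of the mean ratio 0.058). The low SD is therefore in part that of repeated spots and not of different genes. No biological explanation was tested, since the design gives none that differs between dye orientations.

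Several genes had probes that disagreed, such as Car2, Hao2, Slc38a2, Cdk1, Cyp4f6 and Fabp3. In 16 genes with a probe past 1.5-fold and another within 0.2 of 0, the probe near 0 had the lower dye component in 15, a share of 0.9375 (exact 95% interval 0.698 to 0.998). Large changes sat mostly at high dye components whatever the gene: over 84101 pairs of different genes chosen in the same way the share was 0.852, and a test of the 0.9375 against it gave p = 0.494 (exact binomial test, two-sided). Whether the ratio is compressed at the dimmer probe of a gene therefore stays open. Rxrg was the exception, with a dye component of 0.04 at both probes. Probes that detect different transcripts, or clones with a wrong symbol, were not tested and stay open.

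Unnamed spots at 18 positions recurred in each of 16 blocks of the array, 288 spots in all, and their values are given without explanation. Those at positions 89 to 91 (48 spots) averaged 0.00 ± 0.03 (SD) as deposited, and 55 of 64 means per block and array lay within 0.01 of 0. Those at positions 102 to 104 (48 spots) averaged 0.25 ± 0.05 with a dye component of -1.23, and those at positions 105 to 107 (48 spots) 0.44 ± 0.08 with a dye component of -0.63. Those at positions 108 to 110 (48 spots) averaged 0.99 ± 0.06, 1.99-fold if the base of the logarithm is 2. Those at positions 111 to 116 (96 spots) averaged 0.21 ± 0.06 with a dye component of -1.43. The labels do not say what these spots are. With the spots at positions 89 to 91 as the zero, which is that of the deposited values, 8.61% of the calls were lower in place of 71.1% with the array median, so the split of the calls depends on that choice.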
